A study of Bos taurus with 30 samples.

How the data were processed

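RNA from caruncular and intercaruncular endometrium of cows was compared on 30 arrays with 2 colours. Per the labels' protocols, total RNA was reverse transcribed with aminoallyl nucleotides and coupled to Cy3 or Cy5, with Cy3 on channel 1 and Cy5 on channel 2. In 14 of 15 animals the dyes of the tissues were exchanged between the 2 arrays, per the labels. The deposited values are log ratios of the channels of each array, here taken as log2, already normalised within the array by the authors. The method of normalisation, the base of the logarithm and the order of the channels are not stated in the labels. The values are signed, reach 7.14 and -6.95, and are centred, with array medians between -0.0205 and 0.019. The SD of an array over spots lay between 0.228 and 0.816. Scanner intensities were not used here, so signal over background is not known.

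Each of 27648 spots carried a value or a blank. In 8750 of 8750 annotated pairs, adjacent spots shared their accession, so 2 adjacent spots were averaged into 1 of 13824 probes. Within arrays the duplicate spots correlated at r between 0.562 and 0.940 over probes. Gene names came from the platform annotation that accompanies the values: 8645 probes had 1 symbol, 105 had several and 5074 were not listed and are unnamed here. Of the annotated probes, 8620 had a gene ID in the bovine reference table of assembly ARS-UCD2.0, which updated 0 symbols. Probes with several symbols were tested but not named. No coordinates are given, since the files name no genome build.

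Whether the values are dye ratios or ratios already turned to the tissues was decided by a rule set before the data were examined. The rule takes the median, over 14 animals with both dye orientations, of the correlation between the 2 arrays' deviations from the mean of their orientation. It was 0.00871, with 7 of 14 above 0, so the values were taken as already turned, by a narrow margin. Comparisons made after the data were examined bear on that choice. Taken as tissue ratios, the mean of the SCNT and IVF-ET animals correlated at 0.0456 between neighbouring probes and at -0.0324 (Spearman) with print order. The effect that follows the dyes correlated at 0.478 and -0.492, and lay in the labelled direction on 10 AI, 9 IVF-ET and 9 SCNT arrays of 10 each. The direction was to be called from the list of glandular genes, which had a median of 0.0226 over all animals, at percentile 87.6 of 10000 random lists of its size, and -0.02, 0.15 and 0.08 in AI, IVF-ET and SCNT animals, at percentiles 18.6, 99.9 and 97.9. It was taken as not deciding, since the groups lay on different sides, so no direction is given. IVF-ET replicate 3 was labelled with the same orientation on both arrays, which correlated at -0.343. By the rule set beforehand it was left out, and 28 arrays of 14 animals entered the fit.

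Each array was centred on its median. The dye effect of a probe, estimated from animals with both orientations, was taken off, and the 2 arrays of an animal were averaged, so that the animal is the replicate. A probe was tested if at least 4 of 5 animals of AI and SCNT, and 3 of 4 of IVF-ET, had a value, which left 13818. limma 3.58.1 in R 4.3.3 fitted a mean per group with lmFit and eBayes, with 1 spread per probe shared by the groups. The group means against 0, their mean, their pairwise differences and an F test over the 3 groups were tested, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Each array holds both tissues of an animal, so the ratio is paired within the animal. The numbers of the replicates name different animals in each group. The arrays of each group have adjacent numbers in the labels, so array order and group cannot be told apart.

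Genes were named by a rule fixed before the data were examined. For all animals and for AI it takes the 10 largest changes in each direction past the threshold with every animal on 1 side (at least 14 of 15 over all animals, applied as 13 of 14 after the exclusion). For IVF-ET and SCNT it takes 5 in each direction, again past the threshold and with every animal of the group on 1 side. For differences between groups it takes 10 in each direction, or the 5 with the smallest p where none passes. From each list it takes up to 4 members past the threshold over all animals with the largest change. Since none passed over all animals, this last part was applied to SCNT animals, a choice made after the data were examined. A gene with several probes is represented by the probe with most values. Genes of the trophoblast, interferon and AI patterns named outside this rule, and the members named in the closing section, were chosen after their values were seen.

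The 24 gene lists were gland and secretory epithelium, pan-epithelial, stromal fibroblast and matrix, smooth muscle, endothelium and vessels, leukocytes, red blood cells, interferon-stimulated, antigen presentation, complement and coagulation, prostaglandin and oxytocin, steroid signalling, implantation transcription and growth factors, IGF axis, WNT signalling, cell adhesion, nutrient transport, glycolysis and hypoxia, cell cycle, unfolded protein response, imprinted and conceptus genes, ribosomal proteins and oxidative phosphorylation. They were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes.

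The other settings planned were values not centred, values centred and scaled, no dye effect taken off, arrays as samples with the correlation within an animal (0.0682), only the groups of the comparison, another filter on missing values in either direction, a robust variance model, weights per animal, a minimum fold of 1.5, the mean over the probes of a gene for the lists, IVF-ET replicate 3 kept as labelled or with its second array turned, and each animal left out in turn. Chosen after the data were examined were the AI values with the sign turned, a running median over 101 adjacent probes taken off each array, the values read as dye ratios, and IVF-ET replicate 3 kept with its first array turned.

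The procedure was tested on simulated data with shifts of 0.5 and 1 (log2) in known probes among 13818. For SCNT it recovered 57 and 94 of 100 probes with 9 false calls, for IVF-ET 48 and 98 with 3, and for AI 62 and 97 with 6. For the differences it recovered 30% and 89% of 200 probes for IVF-ET against AI, 32% and 92% for SCNT against AI and 28.5% and 90% for SCNT against IVF-ET. Of 24 simulated lists, the 1 shifted list was called and 0 others were. The simulated genes varied independently, whereas the interferon-stimulated list had an estimated correlation of 0.372. The simulation therefore does not show how often lists of correlated genes are called falsely. All simulated animals had the same spread, unlike SCNT replicate 5, whose SD over probes was 0.702.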

Results

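The data came from 30 hybridisations of RNA from the bovine uterine lining, with 2 arrays for each of 15 animals. Each array held both kinds of endometrium of 1 animal: the caruncle, the aglandular site where the placenta attaches, and the intercaruncular tissue between those sites, which carries the glands. There were 5 animals with a pregnancy from artificial insemination (AI), 5 with an embryo fertilised in vitro and transferred (IVF-ET) and 5 with an embryo made by somatic cell nuclear transfer (SCNT), the method used for cloning. Each value is a log ratio of the 2 tissues of an animal, taken here as log2. The base of the logarithm is not given in the labels, so every fold below rests on that reading. Of 13824 probes, 13818 were tested. The arrays held between 26744 and 27643 spots with a value. The number of animals limits the precision, and so does the weak agreement between the 2 arrays of an animal. With the dye effect taken off, these correlated over probes at a median of r = 0.123 across the 15 animals, and at 0.791 in SCNT replicate 5.

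Which tissue stands above the line of the ratio is not settled. The deposited values were taken as ratios already turned to the tissues, by a rule set beforehand that was met by a narrow margin: a median correlation of 0.00871 between the 2 arrays of an animal, after the mean of each dye orientation was taken off, with 7 of 14 animals above 0. Read as dye ratios, they give 0 probes in SCNT animals, 1 in IVF-ET, 361 in AI and 2125 over all animals. Under that reading the effect that follows the dyes stands as the tissue difference. That effect correlated at -0.492 (Spearman) with print order, against -0.0324 for the mean of SCNT and IVF-ET animals taken as tissue ratios. The 2125 and 361 probes may therefore in part follow print order, which was not tested. The glandular gene list, which the intercaruncular side should favour, had a median of 0.02 over all animals, at percentile 87.6 of random lists, and was taken as not deciding the direction. By group it lay at percentile 99.9 in IVF-ET, 97.9 in SCNT and 18.6 in AI animals. Values are therefore given as the positive or the negative side of the deposited ratio, which is the same tissue side throughout only if the groups were deposited alike. The AI animals raise a doubt on that point. Across probes, which are not independent replicates, the mean AI profile correlated at r = -0.291 with the SCNT profile and at r = -0.271 with the IVF-ET profile, while IVF-ET and SCNT correlated at r = 0.454. Single AI arrays lay between r = -0.563 and 0.466 with the SCNT profile. Results that use the AI group are therefore given as deposited and with its sign turned, for the counts, the named genes and the list calls. Both arrays of AI replicate 5 lay above 0 with the SCNT profile (r = 0.185 and 0.142), so a turned sign sets that animal against it. IVF-ET replicate 3, whose arrays carried the same dye label and opposed each other (r = -0.343), was left out, which leaves 14 animals.

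**Figure D1:**
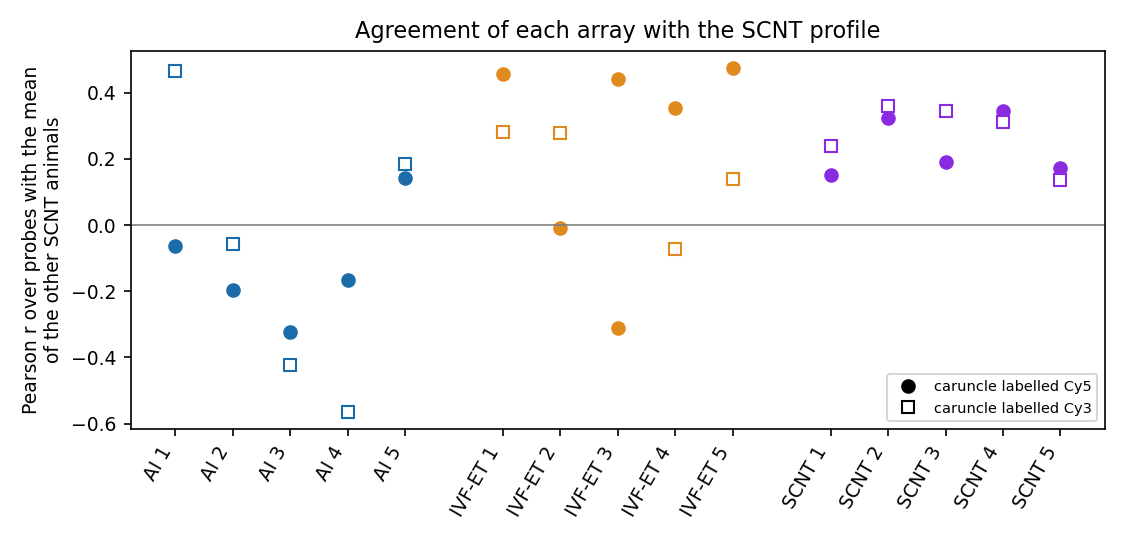
Pearson correlation over probes of each array with the mean of the other SCNT animals (vertical axis, no unit), by animal, with filled circles for caruncle on Cy5 and open squares for caruncle on Cy3. All 10 SCNT arrays lie above 0, 7 of the 10 AI arrays lie below 0, and the 2 arrays of IVF-ET replicate 3 lie on opposite sides.

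The first comparison asks which genes differed between the caruncular and intercaruncular endometrium of SCNT pregnancies. On the negative side stood H19, an imprinted non-coding RNA, at -2.47 ± 0.34 (SE from limma, n = 5, a 5.53-fold ratio between the tissues). With it stood PTN, a secreted growth factor (-1.86 ± 0.33), the collagen chains COL3A1 (-1.70 ± 0.31) and COL6A3 (-1.69 ± 0.19), and the gap junction protein GJA1 (-1.68 ± 0.27). On the positive side stood HPGD, the enzyme that inactivates prostaglandins, at 1.61 ± 0.29 (a 3.06-fold ratio), and LOC613966, with no name in the annotation, at 1.61 ± 0.26. GUCY1B1, a subunit of the nitric oxide receptor, was at 1.41 ± 0.26, the endosomal channel MCOLN2 at 1.26 ± 0.25 and the matricellular growth factor CCN2 at 1.18 ± 0.20. Each of these 10 genes lay on its side in 5 of 5 animals, with adjusted p between 0.00262 (COL6A3) and 0.0173 (MCOLN2). Both were conditions of being named. With limma, 253 probes passed an adjusted p of 0.05, 107 on the positive and 146 on the negative side. They named 176 genes, and 73 of the probes had no gene name. Leaving out SCNT replicate 1, 2, 3 or 4 left 2, 95, 108 and 167 probes, and fitting the SCNT animals alone left 74. No probe passed with the values read as dye ratios, or with IVF-ET replicate 3 kept and its second array turned, which changes the spread shared by the groups. The second array correlated at r = 0.453 with the other IVF-ET animals and the first at r = -0.458. Turning the second therefore sets both arrays against that group. With the first array turned instead, the 10 genes named here kept their calls.

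The annotation gives these genes by their gene ID: H19 is 100126192, PTN 280904, COL3A1 510833, COL6A3 530657, GJA1 281193, HPGD 512259, LOC613966 613966, GUCY1B1 282433, MCOLN2 532671 and CCN2 281103.

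**Figure D2:**
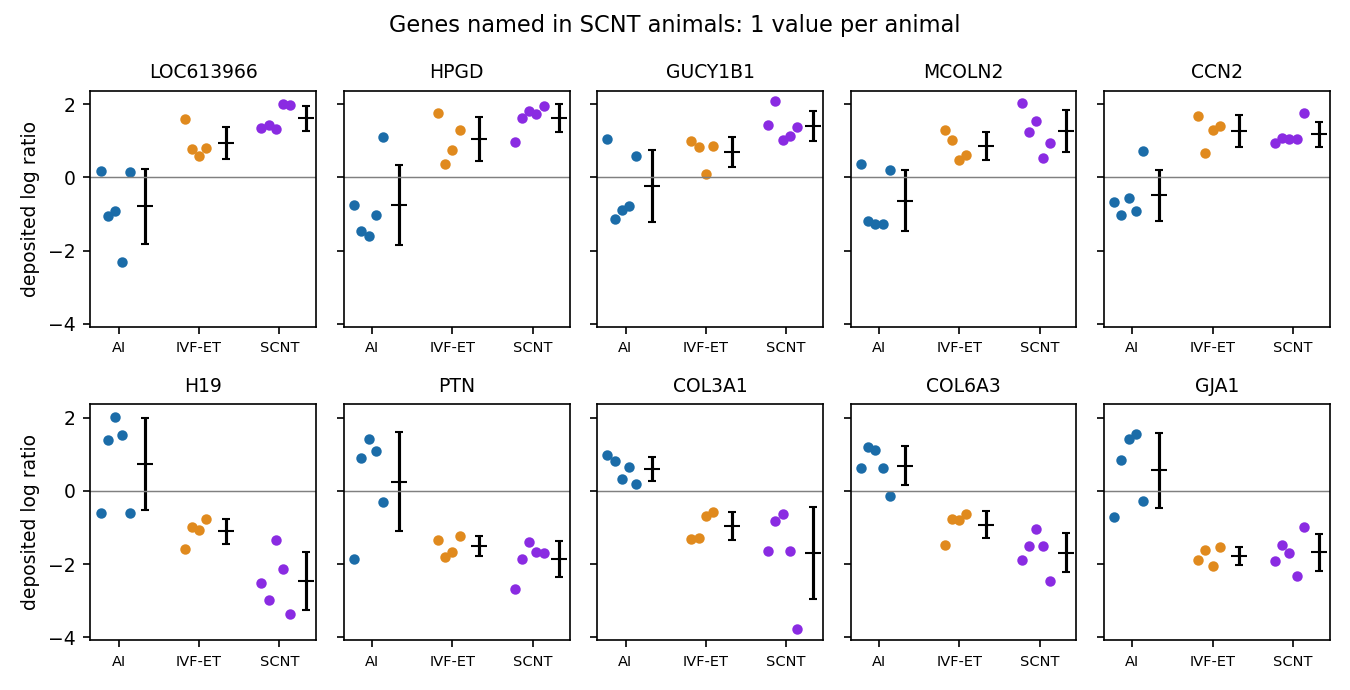
Deposited log ratio (vertical axis, taken as log2) of the 10 genes named in SCNT animals, with 1 point per animal and the group mean with its SD as a bar. All SCNT animals lie on 1 side of 0 in each of the 10 panels, which the naming rule required, and all IVF-ET animals lie on that side too. COL3A1 lies on the other side in 5 of 5 AI animals.

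Gene lists fixed beforehand also divided between the sides in SCNT animals. Of 40 measured genes of stromal fibroblasts and matrix, 10 passed on the negative side, 1 (CCN2) on the positive side and 29 did not pass, with a list median of -0.37. The 10 included COL3A1, COL6A3 and the secreted WNT inhibitors SFRP1 (-1.31 ± 0.23) and SFRP2 (-1.27 ± 0.20). Adjusted over the list alone, 19 passed on the negative side and 1 on the positive side. The list's adjusted p was 7.61e-10 with camera and remained under the threshold with an estimated correlation (adjusted p = 0.0297). Of 28 epithelial genes, 3 passed, all on the positive side, and the median was 0.27 (adjusted p = 2.79e-06, and 0.249 with an estimated correlation). They were EZR, which links the membrane to the cytoskeleton (0.98 ± 0.23), the desmosomal protein DSP (0.63 ± 0.14) and the tight junction protein OCLN (0.51 ± 0.12). Adjusted over the list alone, 10 epithelial genes passed on the positive and 1 on the negative side. No other list among the 8 called in SCNT animals kept its call with an estimated correlation.

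Genes of glycolysis, imprinted genes and interferon-stimulated genes were also among the lists with a call in SCNT animals, each with a median on the negative side. Of 30 genes of glycolysis and hypoxia, 4 passed on the negative and 1 on the positive side (11 and 1 when adjusted over the list alone). Among them were the haem-degrading enzyme HMOX1 (-0.62 ± 0.12), the vasodilator peptide ADM (-0.61 ± 0.15) and the glycolytic enzyme PGK1 (-0.60 ± 0.13, with 7 of 7 probes of that sign), against PFKFB3, a regulator of glycolysis (0.57 ± 0.11). The list median was -0.25, with an adjusted p of 0.000544 (0.197 with an estimated correlation). Of 22 imprinted genes, 2 passed on the negative side, H19 and the fetal growth factor IGF2 (-0.78 ± 0.14), and 10 when adjusted over the list alone. Their median was -0.12, with an adjusted p of 0.00113 (0.0808 with an estimated correlation). Of 42 interferon-stimulated genes none passed by itself, nor when adjusted over the list alone, while the median was -0.22 and the adjusted p 0.000146 (0.513 with an estimated correlation). SCNT replicate 5 lay lowest, with a list median of -0.37.

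Trophoblast genes, ribosomal protein genes and genes of oxidative phosphorylation also had negative medians in SCNT animals. Of 24 conceptus genes none passed over all genes and 4 passed on the negative side when adjusted over the list alone. The median was -0.18 and the adjusted p 0.0147 (0.513 with an estimated correlation). SCNT replicate 3 carried most of that shift, with a list median of -0.77, and without it the adjusted p was 0.572. The call was also lost without SCNT replicate 1 or 4. For 56 ribosomal protein genes the median was -0.19 (adjusted p = 0.000315, and 0.439 with an estimated correlation), and for 72 genes of oxidative phosphorylation it was -0.09 (adjusted p = 0.0031, and 0.462 with an estimated correlation). No single member of these 2 lists passed, over all genes or over the list alone. Without SCNT replicate 2 the adjusted p of oxidative phosphorylation was 0.154.

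Single genes also passed in SCNT animals from lists that had no call. Of 32 implantation genes, the homeobox factor MSX1 was at 1.16 ± 0.22 (2 of 2 probes of that sign), the activin-binding protein FST at -1.08 ± 0.26 and HOXA9 at -0.76 ± 0.17 (list adjusted p = 0.472). Of 16 prostaglandin and oxytocin genes, HPGD passed on the positive side and the prostaglandin synthase PTGDS on the negative (-0.97 ± 0.21, list adjusted p = 0.86). Of 15 genes of the IGF axis, IGF2 and the binding protein IGFBP6 (-1.35 ± 0.26) passed (list adjusted p = 0.0984). Of 24 WNT genes, SFRP1, SFRP2 and the transcription factor TCF7L2 (-0.49 ± 0.10) passed on the negative side (list adjusted p = 0.0984). The proteoglycan SDC2 (-0.61 ± 0.10) was the member of 32 adhesion genes to pass, and the fatty acid transporter SLC27A6 (1.23 ± 0.28, positive in 4 of 5 animals) that of 36 nutrient transport genes. The list adjusted p values were 0.684 and 0.472. Adjusted over the list alone, implantation genes gave 3 on each side, prostaglandin genes 1 on each side, the IGF axis 3 and WNT genes 3 on the negative side, adhesion 1 positive and 2 negative, and nutrient transport 1 positive.

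**Figure D3:**
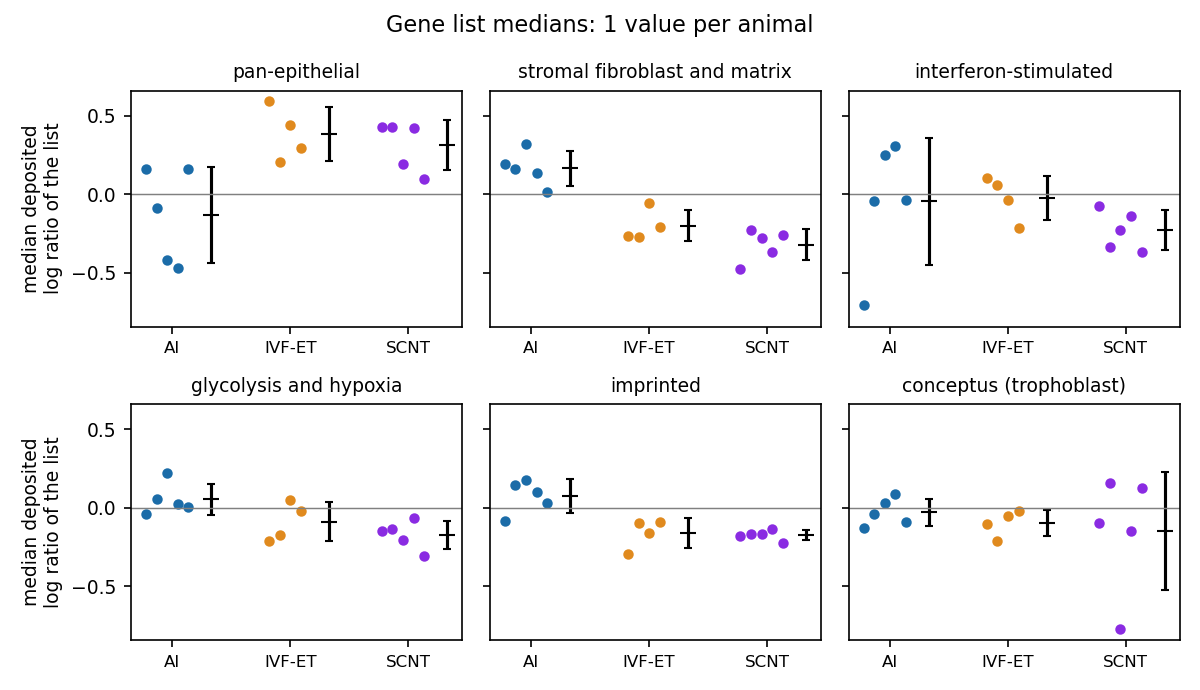
Median deposited log ratio (vertical axis, taken as log2) of 6 gene lists, with 1 point per animal and the group mean with its SD as a bar. The medians of stromal and imprinted genes lie below 0 in all IVF-ET and SCNT animals, and the stromal median lies above 0 in all AI animals; the conceptus median of -0.77 is SCNT replicate 3.

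In IVF-ET pregnancies the same question gave means on the same sides for the genes named in SCNT animals. GJA1 was at -1.77 ± 0.24 (SD, n = 4), PTN at -1.51 ± 0.28, H19 at -1.10 ± 0.34, COL3A1 at -0.96 ± 0.39 and COL6A3 at -0.92 ± 0.37. On the positive side CCN2 was at 1.26 ± 0.44, HPGD at 1.05 ± 0.61, LOC613966 at 0.94 ± 0.45, MCOLN2 at 0.85 ± 0.38 and GUCY1B1 at 0.69 ± 0.40. All 10 lay on that side in 4 of 4 animals, and none passed the threshold. With limma, 0 of 13818 probes passed in IVF-ET animals, where 1099 had an unadjusted p under 0.05, and the smallest adjusted p was 0.144. The IVF-ET animals fitted alone gave 105 probes, and keeping replicate 3 with its first array turned gave 79. Leaving out AI replicate 1, AI replicate 5 or SCNT replicate 5 gave 10, 1 and 21.

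Epithelial genes were the IVF-ET list with the largest shift, at a median of 0.39 over 28 genes (adjusted p = 1.67e-11). The complement and coagulation list had a median of 0.12 over 31 genes (adjusted p = 0.00942). On the negative side were stromal and matrix genes (-0.18, adjusted p = 1.15e-05), oxidative phosphorylation (-0.13, adjusted p = 9.51e-07), ribosomal proteins (-0.13, adjusted p = 2.27e-05) and imprinted genes (-0.12, adjusted p = 0.00517). None of these 6 calls was kept with an estimated correlation, where the adjusted p was 0.0972 for the epithelial, stromal and imprinted lists, 0.198 for complement, 0.159 for oxidative phosphorylation and 0.288 for ribosomal proteins. No member passed over all genes. Adjusted over the list alone, 8 epithelial and 2 complement genes passed on the positive side, 7 stromal genes and 1 imprinted gene on the negative side, with 1 stromal gene on the positive side.

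The difference between SCNT and IVF-ET pregnancies was tested directly. No gene passed, and the genes with the smallest p were IGHG1, an immunoglobulin heavy chain (-1.78 ± 0.49), RAB33A, a small GTPase of vesicle transport (-0.54 ± 0.13), the calcium pump ATP2A1 (0.52 ± 0.13), the elongation factor SUPT6H (-0.49 ± 0.12) and FAF2 (-0.43 ± 0.11), each with an adjusted p of 0.915. IGHG1 was at -3.73 in SCNT replicate 5 and between -1.39 and -0.40 in the other SCNT animals, against -0.49 to 0.74 in IVF-ET, and without SCNT replicate 5 its difference was -1.23. With limma, 0 of 13818 probes passed and 610 had an unadjusted p under 0.05. Interferon-stimulated genes (median difference -0.24, adjusted p = 0.00042) and stromal genes (-0.21, adjusted p = 0.0226) lay further to the negative side in SCNT animals, and neither call was kept with an estimated correlation (adjusted p = 0.746 for both). No member of either list passed, over all genes or over the list alone. The call on 1 of the 2 lists was lost without IVF-ET replicate 4 or 5, or SCNT replicate 1 or 4.

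In AI pregnancies no gene passed. Stromal and matrix genes had a median of 0.19, smooth muscle genes of 0.15, imprinted genes of 0.08 and epithelial genes of -0.14 in the deposited values, with camera adjusted p of 2.35e-08, 0.00103, 0.0207 and 0.00103. With an estimated correlation these were adjusted p = 0.053, 0.263, 0.257 and 0.561. COL3A1 was positive in 5 of 5 AI animals (0.60 ± 0.33, SD), while H19 was positive in 3 (1.38 to 2.02, the others -0.61 and -0.60) and HPGD negative in 4 (-1.60 to -0.76, with replicate 5 at 1.10). The 2 arrays of AI replicate 1 opposed each other, at -1.07 and 3.03 for COL3A1, -2.14 and 0.91 for H19, 1.79 and -3.32 for HPGD and -0.70 and 0.85 for the stromal median, so the side of that animal is that of a mean of opposed arrays. No listed member passed over all genes, and 3 stromal genes passed on the positive side when adjusted over the list alone. With limma, 0 of 13818 probes passed (361 with the values read as dye ratios) and 605 had an unadjusted p under 0.05. With the sign of the group turned, these counts are the same and the sides are exchanged. The values of the AI animals spread widely, and without AI replicate 1 the lists with a call went from 4 to 9.

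Over all animals, the answer on the shared regional difference depended on the sign of the AI group. As deposited, no gene passed. With the AI sign turned, an alternative chosen after the data were examined, genes passed on both sides. That alternative was chosen because the AI mean correlated below 0 with the other groups in these same values. Turning the sign therefore raises agreement among the groups by construction, and the calls are no separate evidence of a shared regional difference. On the negative side COL6A3 was at -1.10 ± 0.12 (SE), COL3A1 at -1.09 ± 0.18, SFRP1 at -0.97 ± 0.14, the retinol-binding protein receptor STRA6 at -0.91 ± 0.12 and SNAI2, a repressor of epithelial genes, at -0.64 ± 0.07. HPGD (1.14 ± 0.17), CCN2 (0.98 ± 0.12), the calcification inhibitor MGP (0.94 ± 0.17), SLC27A6 (0.85 ± 0.17) and the tight junction protein CGN (0.58 ± 0.07) lay on the positive side. Each lay on its side in 13 or 14 of 14 animals, which the naming rule required. The other genes named by the same rule were GRB7, SLC22A5, FADS2, the receptor ERBB2 and PFKFB3 on the positive side, between 0.73 and 0.53. On the negative side they were LOC513055, COL1A2, IGFBP6, SPON1 and EMILIN1, between -0.84 and -0.63. The counts with limma were 0 of 13818 probes as deposited (1316 at an unadjusted p under 0.05), 2125 with the values read as dye ratios and 440 with the sign turned, 217 positive and 223 negative. As deposited, the count was 28 without AI replicate 4 and 77 without SCNT replicate 5.

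Gene lists over all animals as deposited gave 10 calls with camera. On the positive side these were the epithelial list (median 0.14, adjusted p = 7.96e-08), endothelium and vessels (0.03, adjusted p = 0.0265) and complement (0.05, adjusted p = 0.0339). On the negative side they were the stromal list (-0.12, adjusted p = 2.41e-05), oxidative phosphorylation (-0.10, adjusted p = 5.6e-07), ribosomal proteins (-0.11, adjusted p = 5.4e-05), interferon-stimulated and conceptus genes (-0.11 each, adjusted p = 0.00136 each), imprinted genes (-0.06, adjusted p = 0.00597) and glycolysis (-0.12, adjusted p = 0.019). With an estimated correlation 0 of them remained, with adjusted p = 0.146 at the lowest. With the AI sign turned, a choice that raises agreement among the groups by construction, there were 8 calls. The stromal list (-0.24) and the imprinted list (-0.14) kept theirs with an estimated correlation (adjusted p = 0.0104 and 0.0267). The other 6 were epithelial, ribosomal protein, oxidative phosphorylation and glycolysis genes, with smooth muscle and WNT genes (adjusted p = 0.0218 each), which had none as deposited. Endothelium, complement, interferon-stimulated and conceptus genes lost theirs (adjusted p = 0.708, 0.177, 0.278 and 0.068). No member passed over all genes as deposited, and 10 stromal genes on the negative side and 8 epithelial genes on the positive side passed when adjusted over the list alone.

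The genes below passed for a difference of the regional ratio between SCNT and AI pregnancies, and were picked by size as deposited. Each has its value as deposited with its SE, then its value with the AI sign turned, where none passed and the order by size was another. The negative side held H19 (-3.21 ± 0.49, turned -1.72), COL6A3 (-2.37 ± 0.27, turned -1.0), COL3A1 (-2.30 ± 0.43, turned -1.09), GJA1 (-2.25 ± 0.38, turned -1.12) and PTN (-2.11 ± 0.47, turned -1.61). On the positive side were LOC613966 (2.41 ± 0.37, turned 0.82), HPGD (2.36 ± 0.41, turned 0.86), MCOLN2 (1.89 ± 0.35, turned 0.63), MGP (1.89 ± 0.40, turned 0.34) and SLC27A6 (1.79 ± 0.39, turned 0.68). The others named were STRA6 (-1.85, turned -0.75), SFRP1 (-1.82, turned -0.80), IGFBP6 (-1.66, turned -1.05), the secreted matrix protein OLFML3 (-1.55, turned -0.86) and SFRP2 (-1.39, turned -1.15). With them were CCN2 (1.67, turned 0.69), GUCY1B1 (1.65, turned 1.18), FRY (1.53, turned 0.77), the interleukin receptor IL6R (1.47, turned 0.61) and MPPED2 (1.32, turned 0.89). With limma, 131 probes passed, 57 positive and 74 negative, and named 84 genes. With the AI sign turned 0 probes passed. Without AI replicates 1 to 5 in turn the count was 268, 39, 5, 7 and 234. Without SCNT replicates 1 to 5 it was 45, 39, 56, 75 and 241, and without IVF-ET replicates 2, 4 and 5, which share the spread, 65, 64 and 69. The SCNT and AI animals fitted alone gave 10.

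Stromal and matrix genes differed between SCNT and AI animals by a median of -0.53 (adjusted p = 1.18e-13), with 10 of 40 passing on the negative side and CCN2 on the positive. Imprinted genes differed by -0.32 (adjusted p = 0.000262), with H19 and 1 further gene of 22. Both calls were kept with an estimated correlation (adjusted p = 0.00848 and 0.0349). The epithelial list (0.47, adjusted p = 1.14e-07), glycolysis (-0.30, adjusted p = 0.000618), ribosomal proteins (-0.25, adjusted p = 0.000618), smooth muscle (-0.29, adjusted p = 0.00389) and WNT genes (-0.19, adjusted p = 0.0254) did not keep theirs, with adjusted p = 0.159, 0.159, 0.381, 0.286 and 0.289. Adjusted over the list alone, 21 stromal, 11 imprinted and 8 glycolysis genes passed on the negative side and 11 epithelial genes on the positive side. With the AI sign turned, 7 lists had a call and none with an estimated correlation: stromal (-0.19, adjusted p = 0.0167), epithelial (0.11, adjusted p = 0.0291), glycolysis (-0.22, adjusted p = 0.0291), ribosomal proteins (-0.13, adjusted p = 0.0322), interferon-stimulated (-0.32, adjusted p = 3e-06), conceptus (-0.27, adjusted p = 0.00577) and oxidative phosphorylation (-0.12, adjusted p = 0.00577). The imprinted list (-0.096, adjusted p = 0.122), smooth muscle and WNT genes (adjusted p = 0.629 each) lost theirs.

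Between IVF-ET and AI pregnancies the named genes that passed were GJA1 (-2.34 ± 0.40, SE, turned -1.21), CCN2 (1.75 ± 0.30, turned 0.78) and SNAI2 (-1.25 ± 0.17, turned -0.0089). With them were CGN (1.07 ± 0.18, turned 0.26), PFKFB3 (1.02 ± 0.17, turned 0.31) and MALSU1, a factor of mitochondrial ribosome assembly (-0.98 ± 0.16, turned -0.17). SNAI2 was positive in 5 of 5 AI animals and negative in 4 of 4 IVF-ET animals, and CGN and PFKFB3 were negative in 5 of 5 and positive in 4 of 4. In AI replicate 1 these are means of opposed arrays (-0.56 and 2.35 for SNAI2, 0.62 and -0.77 for CGN, 0.61 and -1.27 for PFKFB3). With limma, 8 probes passed, 4 on each side, with adjusted p between 0.0327 and 0.0496 for the 6 named genes. The stromal list differed by -0.38 (adjusted p = 2.3e-10, and 0.0274 with an estimated correlation). The epithelial list (0.53), smooth muscle (-0.20), WNT genes (-0.14), imprinted genes (-0.24), ribosomal proteins (-0.17) and oxidative phosphorylation (-0.12) had a camera call with the preset correlation but not with an estimated one. With an estimated one the adjusted p went from 0.0547 (imprinted) and 0.063 (epithelial) to 0.412 (the other 4). Fry gave the epithelial list an adjusted p of 0.0341. With the AI sign turned 0 probes passed, and the stromal list had no call (median 0.0014, adjusted p = 0.967), nor had the smooth muscle, WNT and imprinted lists. The 6 lists with a call, none with an estimated correlation, were then epithelial (0.24, adjusted p = 0.000709), oxidative phosphorylation (-0.14, adjusted p = 8.87e-06), ribosomal proteins (-0.12, adjusted p = 0.023), endothelium (0.09, adjusted p = 0.0188), complement (0.15, adjusted p = 0.019) and conceptus (-0.17, adjusted p = 0.032). Without AI replicate 2, 3 or 4, IVF-ET replicate 1, 4 or 5, or SCNT replicate 1, 3 or 4 the count was 0, and without IVF-ET replicate 2 or SCNT replicate 2 it was 1. Without AI replicate 1, AI replicate 5 or SCNT replicate 5 it was 26, 25 and 37.

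A single test of any difference among the 3 kinds of pregnancy passed for 30 probes, which named 23 genes, and 1408 probes had an unadjusted p under 0.05. LOC613966 (adjusted p = 0.0273) and HPGD (adjusted p = 0.0484) were among them. With the AI sign turned the count was 0. Without AI replicates 1 to 5 in turn it was 92, 5, 2, 6 and 104, without IVF-ET replicates 2, 4 and 5 it was 8, 10 and 7, and without SCNT replicates 1 to 5 it was 7, 5, 16, 15 and 113.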

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

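Of the tests in this part, the removal of the print-order trend and the second list of trophoblast genes were set before their results were seen. The tests of the AI profile, of the extracts and the channels of AI replicate 1 and of the glycoprotein family, in the second list too, were chosen only after the results were seen.

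The mean regional profile of the AI animals ran opposite to that of SCNT and IVF-ET animals, but not every AI animal did. With the SCNT profile, both arrays lay below 0 in AI replicates 2 (r = -0.058 and -0.196), 3 (-0.324 and -0.422) and 4 (-0.563 and -0.166). Both arrays of replicate 5 lay above 0, and those of replicate 1 were split (0.466 and -0.063). Turning the sign of the whole group therefore turns replicate 5 away from the SCNT profile. With the values read as tissue ratios, a sign turned after the ratios had been formed would also turn the dye effect, yet over the AI arrays that effect kept its labelled direction, with a median correlation of 0.324. For an exchange of tissues or dyes in all AI animals, 3 AI arrays, 1 of replicate 1 and both of replicate 5, correlate above 0.1 with the SCNT profile (r = 0.466, 0.185 and 0.142). They do not decide on it, since the bound of 3 arrays was set after the values were seen. Of the IVF-ET arrays 3 lie below 0. Array 1 of replicate 2 (r = -0.0093) and array 2 of replicate 4 (r = -0.072) lie near 0. The other is array 1 of the left-out replicate 3 (r = -0.310), an animal whose dye labels are themselves in doubt. What stays open is a regional difference of the other sign in AI pregnancies (r = -0.291 between the group means). Also open are an exchange in all animals, one in some animals, which was not tested, and the array order, which follows the groups. The AI profile may therefore be biological or technical, and these cannot be told apart here.

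Interferon-stimulated genes stood far on the negative side on array 2 of AI replicate 1 and near 0 on array 1 of the same animal: ISG15 was at -4.82 against -0.31, RSAD2 at -4.64 against -0.12, MX1 at -3.99 against -0.12 and MX2 at -3.38 against -0.03. Arrays 1 and 2 also opposed each other for HPGD (1.79 and -3.32), H19 (-2.14 and 0.91), COL3A1 (-1.07 and 3.03) and the stromal list median (-0.70 and 0.85), and without this animal 268 rather than 131 probes passed between SCNT and AI animals. The interferon list medians of these arrays differed by 1.41, where no other animal reached more than 0.361. The pattern was picked for this difference, so the difference does not decide whether both arrays held the same pair of RNA extracts. With the print-order trend removed the median on array 2 was -1.46, against -1.53 before, so that trend was not the source. Other RNA in 1 channel of 1 of the arrays may be the source: the arrays correlated at r = 0.0171, but the median animal reached no more than 0.123, so that value leaves it open, and no biological explanation was tested. Low values were not confined to this animal. In SCNT replicate 5 ISG15 (-3.08 and -3.06) and MX2 (-2.90 and -2.52) were low on both arrays, while MX1 (0.40 and -0.36) and RSAD2 (0.26 and -0.47) were near 0.

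Several trophoblast genes stood far on the negative side on the arrays of SCNT replicates 3 and 4, although the list median on array 2 of replicate 4 was 0.0079: PAG2, a pregnancy-associated glycoprotein, was at -2.76 and -2.88 in replicate 3 and at -2.69 and -2.14 in replicate 4, and the trophoblast Kunitz protein TKDP1 at -1.69, -3.76, -3.56 and -1.21. In replicate 3, 9 of 24 conceptus genes lay below -1 on both arrays, in replicate 4 there were 2, and in each of the other animals 0. The print-order trend is argued against, since the list median over the 4 arrays was -0.535 without it and -0.475 with it. Cross-hybridisation within the glycoprotein family as the whole source is argued against by conceptus genes outside that family (16 genes, median -0.258). Of them TKDP1, TKDP4, IFNT2, HAND1 and PRP4 lay below -1 on both arrays of replicate 3, and TKDP1 on both of replicate 4. This count of 6 holds TKDP1 once per animal. Of random lists 0 of 10000 reached it, but these animals were picked for their low conceptus genes, so that share is no separate support. Trophoblast RNA in 1 of the tissue samples may be the source: a second list of 15 trophoblast genes had a median of -0.132, at percentile 0.51 of random lists, with PAG19 at -2.11, PAG18 at -0.93 and SLC2A3 at -0.64, but the 11 genes outside the glycoprotein family had a median of -0.035, at percentile 26.8, so the shift of that list rests on the family and does not decide. For the 8 members of the family (median -0.814) cross-hybridisation stays open, as RNA of several members gives the same values, and neither source can be told apart from a difference between these pregnancies, which was not tested.

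Single animals stood far from the others of their group in 10 of 149 groups of values, where chance gives about 5%. SCNT replicate 5 had an SD over probes of 0.702, against 0.216 to 0.320 in the other SCNT animals. It also stood apart for CCN2 (1.77, the others 0.94 to 1.07), IL6R (-0.080, the others 1.11 to 1.44), HOXA9 (-1.75, the others -0.67 to -0.39) and the median of cell cycle genes (0.18, the others -0.09 to -0.05). AI replicate 5 stood apart for CCN2 (0.71, the others -1.02 to -0.55) and MGP (0.49, the others -1.32 to -0.82), and AI replicate 1 for MALSU1 (-0.060, the others 0.45 to 0.59). AI replicate 3 had a leukocyte median of 0.22 (the others -0.03 to 0.02), and IVF-ET replicate 2 a median of implantation genes of 0.043 (the others -0.04 to -0.03).

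The regional ratio differed between groups, by limma's test of the difference, for 26 pairs of gene and comparison, each of which loses its call when the AI sign is turned. The turned values lay between 0.34 (MGP) and 1.18 (GUCY1B1) and between -1.72 (H19) and -0.75 (STRA6) for SCNT against AI. For IVF-ET against AI they lay between -1.21 (GJA1) and 0.78 (CCN2), with SNAI2 at -0.0089. Between SCNT and AI animals the differences were 2.41 for LOC613966, 2.36 for HPGD, 1.89 for MCOLN2, 1.89 for MGP, 1.79 for SLC27A6, 1.67 for CCN2, 1.65 for GUCY1B1, 1.53 for FRY, 1.47 for IL6R and 1.32 for MPPED2. On the negative side they were -3.21 for H19, -2.37 for COL6A3, -2.30 for COL3A1, -2.25 for GJA1, -2.11 for PTN, -1.85 for STRA6, -1.82 for SFRP1, -1.66 for IGFBP6, -1.55 for OLFML3 and -1.39 for SFRP2. Between IVF-ET and AI animals they were 1.75 for CCN2, 1.07 for CGN, 1.02 for PFKFB3, -2.34 for GJA1, -1.25 for SNAI2 and -0.98 for MALSU1.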

How the results depend on the processing

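The sign of the AI group, the removal of the print-order trend, the values read as dye ratios and IVF-ET replicate 3 with its first array turned were chosen after the data were examined. For the named genes, 1208 of 1226 values under other settings kept their direction, 881 of them their side of the threshold, and 327 lost the threshold. Part of this was fixed in advance. A group mean hardly depends on animals of other groups: H19 in SCNT was at -2.47 without AI replicate 1 and with the AI sign turned. The genes named between SCNT and IVF-ET had no call to lose. The 18 reversed values all came from reading the values as dye ratios: in SCNT animals HPGD -0.14, GUCY1B1 -0.057, MCOLN2 -0.14, CCN2 -0.12, H19 0.42, PTN 0.33, COL3A1 0.30 and COL6A3 0.12; between SCNT and AI MPPED2 -0.064, PTN 0.10, SFRP1 0.050 and IGFBP6 0.18; between IVF-ET and AI PFKFB3 -0.069; between SCNT and IVF-ET RAB33A 0.27, SUPT6H 0.31, ATP2A1 -0.23, FAF2 0.23 and IGHG1 0.13. Read so, 2125 probes passed over all animals, 361 in AI, 1 in IVF-ET, and 0 in SCNT, in both differences against AI and among the 3 groups, with 0 lists in SCNT.

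Counts of probes that moved by over 1.5 times were as follows, and the cause was not tested except where given. Over all animals, where 0 passed, there were 17 with scaled arrays, 128 with arrays as samples, 149 with weights, 440 with the AI sign turned, 1 without the print-order trend and 81 with IVF-ET replicate 3 kept and its first array turned. In IVF-ET, where 0 passed, there were 21 with arrays as samples, 105 with that group alone, 234 with weights and 79 with that first array turned. In SCNT, 253 became 510 with arrays as samples, 740 with weights, 74 with the group alone, 163 at 1.5-fold or more, by construction, and 0 with the second array of IVF-ET replicate 3 turned. Between SCNT and AI, 131 became 289, 266 with weights, 10 with these groups alone, and 0 with that second array or the AI sign turned. Between IVF-ET and AI, 8 became 20, 66 with weights, 18 with these groups alone, 5 with no filter, 33 with the first array turned, 1 with replicate 3 as labelled, and 0 with scaled arrays, the second array turned, the AI sign turned or no print-order trend. Among the 3 groups, 30 became 140, 112 with weights, 65 with the first array turned, 16 without the print-order trend, and 0 with the second array or the AI sign turned. With an estimated correlation 1 of 8 lists in SCNT kept its call. The second array of IVF-ET replicate 3 correlated at r = 0.453 with the other IVF-ET animals and the first at r = -0.458. Turning the second therefore sets both arrays against that group.

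Leaving out each animal in turn gave 0 to 77 probes over all animals, 0 in AI, 0 to 21 in IVF-ET, 2 to 325 in SCNT, 5 to 268 between SCNT and AI, 0 to 37 between IVF-ET and AI, 0 between SCNT and IVF-ET, 2 to 113 among the 3 groups, and 7 to 9 lists in SCNT. No paired analysis was possible because the replicate numbers name different animals in each group; the tissues are already paired on each array. Fitting only the groups compared is the same fit for all animals and for the 3 groups. Scanner signal is not given in the sources used here, so its limit is unknown.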

Other observations

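The regroupings of animals in this part were set before their results were seen. The turned AI sign, and the members C1S and SERPING1, were chosen only after the results were seen.

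Lists of leukocytes, vessels, smooth muscle, red blood cells and glands had no call in SCNT animals. Leukocyte genes had a median of 0.03 over 43 genes (camera adjusted p = 0.36), endothelial and vessel genes 0.03 over 29 (adjusted p = 0.472), smooth muscle genes -0.14 over 17 (adjusted p = 0.119) and 5 red blood cell genes -0.06 (adjusted p = 0.548). Glandular genes had a median of 0.08 over 15 (adjusted p = 0.5). No member of these lists passed over all genes, and adjusted over the list alone only glandular genes did, with 2 on the positive and 3 on the negative side. Antigen presentation genes, which display peptides to lymphocytes, had a median of -0.14 over 18 (adjusted p = 0.119), and complement and coagulation genes of 0.02 over 31 (adjusted p = 0.472), with C1S at -1.52 and SERPING1 at -1.15 among members that did not pass. Complement genes gave 2 on each side, and antigen presentation genes 0, when adjusted over the list alone.

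Hormone and stress genes did not pass as lists in SCNT animals either. Steroid signalling genes had a median of -0.10 over 26 (camera adjusted p = 0.392), and fry, which does not compare them with other genes, gave an adjusted p of 0.00872 on the negative side. Of them, 1 passed on the positive and 3 on the negative side when adjusted over the list alone. Fry also called the IGF axis (adjusted p = 0.0237) and WNT genes (adjusted p = 0.0324) on the negative side. It gave no call to interferon-stimulated (adjusted p = 0.16) and conceptus genes (adjusted p = 0.165), which camera called. Genes of the unfolded protein response had a median of 0.03 over 24 (adjusted p = 0.406) and cell cycle genes of -0.05 over 59 (adjusted p = 0.92). Median and mean differed in sign for the gland list (0.08 and -0.06), endothelium (0.03 and -0.02), complement (0.02 and -0.05) and the unfolded protein response (0.03 and -0.02), while for cell cycle genes the test lay on the positive side. For prostaglandin genes they were -0.01 and 0.01. For implantation genes the mean was 0.02 and the median below 0.

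Other groupings of the same animals show how often such counts arise in splits other than the real one. Between SCNT and AI animals 1 of 100 splits, the real one, gave as many as the real 131 probes, the highest other giving 82. For IVF-ET against AI 2 of 100 splits gave at least 8 probes, the highest other giving 15, and for the 3 groups 3 of 100 gave at least 30, the highest other giving 75. Each of these shares is under 5%, but for IVF-ET against AI and for the 3 groups another split gave more probes than the real one. The shares were not adjusted for the number of tests, and these comparisons share the AI animals. They make chance less likely and do not exclude it. For SCNT against IVF-ET the real count was 0, so 100 of 100 splits gave as many by construction and the test says nothing on chance. The highest other gave 1. For gene lists the share was above 5%: 17 of 100 splits gave at least 7 lists for SCNT against AI (highest other 11), 11 of 100 at least 7 for IVF-ET against AI (highest other 10), and 63 of 100 at least 2 for SCNT against IVF-ET (highest other 5).

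For the ratio of a group against 0, the signs of the animals were exchanged in all patterns. In SCNT animals the real pattern was 1 of 16 with as many as 253 probes, the highest other giving 0, and 2 of 16 gave at least 8 lists, the highest other giving 9. In AI animals 16 of 16 patterns, and in IVF-ET animals 8 of 8, gave at least the real 0 probes, which was certain, with 0 as the highest other. These patterns are too few for a share under 5%. Over all animals the real count was 0, so 100 of 100 patterns gave as many by construction, which says nothing on chance. The highest other gave 167 probes, and what gives such a count was not tested.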
